A study of Homo sapiens with 2 samples.

How the data were processed

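RNA of HT-29, an established human colorectal adenocarcinoma cell line, was sequenced in 2 libraries, 1 per group. The genotype label names one as transfected with siIGF-1R, a small interfering RNA (siRNA) against the receptor of insulin-like growth factor 1, and gives no variation for the other, called the control library here. Whether the control received a non-targeting siRNA, a mock transfection or no treatment is not given in the sources used here. The tables name their columns KD and NC. KD was taken as the siIGF-1R library because the series title speaks of a knockdown, and NC as the only other library. Per the labels' protocols, total RNA was harvested with Trizol and made into libraries with an Ion Proton RNA-Seq kit.

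The authors deposited whole-number read counts per gene and a second table of RPKM values (reads scaled by gene model length and library size) for the same 40205 rows. Per the submitters' processing notes the genome build was GRCh38. The aligner, the counting tool, the treatment of reads that match several places and any use of strand are not given in the sources used here. The deposited counts summed to 13780987 reads in the siIGF-1R library and 12271617 in the control library. The deposited RPKM values imply division by 13782085 and 12272551 reads, the whole numbers that best gave whole gene model lengths, which are 1098 and 934 more than the rows hold. Those reads were not analysed here.

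Ratios were computed from the deposited counts, siIGF-1R library over control library, after scaling with the TMM method of edgeR 4.0.16 in R 4.3.3 on rows with at least 1 CPM in 1 or both libraries (15263 rows, called tested genes). The effective library sizes had a ratio of 1.17, and a count of 0.5 was added to each scaled count. Each ratio has a 95% exact conditional binomial (Clopper-Pearson) interval, computed with scipy 1.17.1. These intervals cover counting error only, since reads without molecular identifiers are not independent molecules and 1 library per group holds no biological replicate. No p-value was computed, and every difference compares 2 libraries and has no replicate check. A gene was counted as higher or lower when its ratio was at least 2-fold and its interval lay wholly on that side of 1. A count of 0 allows up to 3 counts, or 0.218 CPM in the siIGF-1R library and 0.245 CPM in the control library.

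Before the data were examined, 39 gene lists were fixed. The median log2 ratio of each list with at least 5 tested members (37 lists) was placed as a percentile among 10000 random lists of the same size, matched member by member on mean abundance in 20 bins. A list was said to stand apart below the 2.5 or above the 97.5 percentile. This describes these libraries and is no test, because genes of a pathway vary together. The genes named were chosen by a rule fixed before the data were examined. It takes IGF1R, the 12 genes with the highest and the 12 with the lowest bound of the interval nearest to 1, up to 4 members of each list with the largest ratios in either direction, and the RNA sensors and mitochondrial apoptosis genes that the series title points to. Ranked genes and list members needed at least 50 reads over both libraries. Unnamed loci, small RNAs of the MIR, SNOR and RNU classes and genes used to tell sex were left out. Some genes that the rule names are not reported here. Genes named outside this rule are said to have been chosen after their values were seen.

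Transcript GC content, 3′ UTRs and coordinates came from the GENCODE 29 annotation of GRCh38, using 1 representative transcript per gene. Of the 15263 tested genes, 13333 (87.4%) had such a transcript. The siRNA sequence in the labels was compared without gaps with 206694 transcripts. For seed sites, genes with a 3′ UTR of at least 50 bases were split by whether it held the heptamer complementary to guide positions 2 to 8, and the difference of median log2 ratios was ranked among all heptamers held by a similar number of genes (within 1.5 times).

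The steps were tested on simulated data, with Poisson counts drawn for the same genes and library sizes and 200 genes altered by known folds. Of the 67 genes raised 3-fold, 97.0% were called, as were 97.0% of the 66 genes lowered to 0.333 of their level and 1.49% of the 67 genes raised 1.5-fold. Among 15015 unaltered genes, 39 were called higher and 51 lower, 10 of these with at least 50 reads. The intervals held the true ratio for 95.2% of genes. Of 100 random lists of 20 genes, 6 fell outside the percentile limits, and all 100 were found after a shift of 0.3 log2. The simulation holds counting error only.

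Alternatives listed before the data were examined were total counts, DESeq2 1.42.0 median-of-ratios factors, upper-quartile scaling, TMM without mitochondrial genes and the 20 most abundant genes, the deposited RPKM values with 0.1 or 1 added, removal of a trend on gene model length, no low-count filter or one of 5 CPM, an added count of 5, folds of 1.5 and 4, intervals wholly beyond 2-fold, the mean in place of the median, matching on length, and other seed definitions. Removal of a lowess trend (statsmodels 0.14.6, fraction 0.3) on GC content, matching on GC content, an mRNA background and a count of mRNA rows were added after seeing the data. Figures were drawn with matplotlib 3.10.9.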

Results

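The transcriptome of HT-29 colorectal adenocarcinoma cells was compared between a library of cells transfected with an siRNA against IGF1R and a control library. IGF1R encodes a receptor tyrosine kinase that signals growth and survival through the PI3K-AKT and ERK pathways. The series title asks whether loss of this receptor engages the viral RNA sensors MDA5 (gene IFIH1) and RIG-I (listed under its older symbol DDX58) and mitochondrial apoptosis. The siIGF-1R library held 13780987 reads over annotated rows and the control library 12271617. At least 1 CPM was reached by 14952 rows in the siIGF-1R library and by 14682 in the control library. Each group has 1 library, so no difference below could be set against a spread between replicates, and the 95% intervals cover counting error only. Among the 5163 genes with the most reads, the log2 ratios had a standard deviation of 0.227. An interval that excludes 1 can thus belong to a ratio within the usual spread across genes. The tallies of intervals above and below 1 were not compared with those of all tested genes.

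IGF1R mRNA was 1.55-fold lower in the siIGF-1R library (interval 1.28 to 1.87), with 197 reads against 260. On the TMM scale this was 13.98 CPM against 21.66 CPM, a log2 ratio of -0.63. The difference was short of the 2-fold rule for a lower gene. At 1.5-fold, 384 tested genes were lower, among them IGF1R. The gene lies on chromosome 15 at 98648539 to 98964530 of GRCh38. Of the 13 tested genes of the IGF receptor axis, 7 had intervals below 1, IGF1R itself included, 6 spanned 1 and none lay above it. Among them, GRB10, an adaptor of the receptor, had a log2 ratio of -0.47, IGF2, a ligand, of -0.35 and IRS1, a docking protein of the receptor, of -0.26. The list's median of -0.14 did not stand apart from abundance-matched random lists (percentile 4.52), although the mean over members (-0.19) and the median after removing a length trend (-0.19) did. That mean includes IGF1R, the siRNA's target and the lowest tested member, so it is in part the knockdown itself. After removal of the GC trend and matching on GC content the median was -0.07, at percentile 14.7.

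The siRNA strand given in the labels, GCCGACACUACUACUACAATT, corresponds to the 19-base DNA target GCCGACACTACTACTACAA. The treatment protocols of both samples print this same strand, so the protocol text does not tie it to the siIGF-1R library. None of the 206694 GENCODE 29 transcripts held this target without mismatch. The closest site in the representative IGF1R transcript, GCCGCCACTACTACTATGC, had 4 mismatches. It lies on the plus strand of chromosome 15 at 98891436 to 98891454, in coding sequence of exon 3 of 21. The substitutions, counted from 1 at the 5′ end of the siRNA strand with the siRNA base first, are A5C, C17T, A18G and A19C. The closest sites in the sense strand of any gene had 3 mismatches and occurred in 9 genes. Read as the passenger strand, the sequence implies the guide UUGUAGUAGUAGUGUCGGC with the seed UGUAGUA. The 781 genes whose 3′ UTR held the matching heptamer TACTACA had a median log2 ratio 0.07 higher than that of the other genes among 11100, at percentile 97.6 of 5010 heptamers of similar frequency. After removal of the GC trend described below the difference was -0.0038, at percentile 87.5. Lower levels of genes with a seed site were thus not detected for the sequence as the labels print it. Since that sequence has no exact match in IGF1R, it may not be the one used, and the seed comparison then says nothing of the siRNA in the cells.

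Across the transcriptome, 234 of 15263 tested genes were at least 2-fold higher in the siIGF-1R library and 144 at least 2-fold lower. Of these, 130 and 74 were mRNA rows. In the simulation, which holds counting error only, the same rule called 39 of 15015 unaltered genes higher and 51 lower. Part of the calls can thus arise from counting error. Interferon-stimulated genes made up 28 of the 234 higher genes, and 7 of the 12 genes with the highest bounds. The other 5 of these 12 were rows with near-identical copies, whose values are uncertain because reads can be assigned to either copy. SLX1A-SULT1A3 had 308 reads against 2 and SLX1A 311 against 34, while the neighbouring copies SLX1B-SULT1A4 (43 against 212) and SLX1B (66 against 244) went the other way. Summed over the 4 rows, the SLX1 family had 728 reads against 492, a log2 ratio of 0.33. The processed pseudogenes RPL18P3, HSBP1P2 and RPS26P10 were higher, with log2 ratios of 5.30, 2.98 and 2.62, whereas their parent genes RPL18, HSBP1 and RPS26, looked up after these values were seen, had log2 ratios of -0.16, 0.04 and -0.08. Among the 12 lowest, NPIPA7 (-2.97), CBWD6 (-1.95) and the pseudogene RPL15P5 (-2.10) are uncertain for the same reason. The membrane proteolipid gene MALL was 3.34-fold lower (interval 2.79 to 4.03), with 159 reads against 453. Rows of 7SL RNA, the RNA of the signal recognition particle, were also among the lowest, with log2 ratios of -3.07 for RN7SL2, -2.13 for RN7SL1, -2.47 for RN7SL3 and -3.82 for RN7SL5P.

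**Figure D1:**
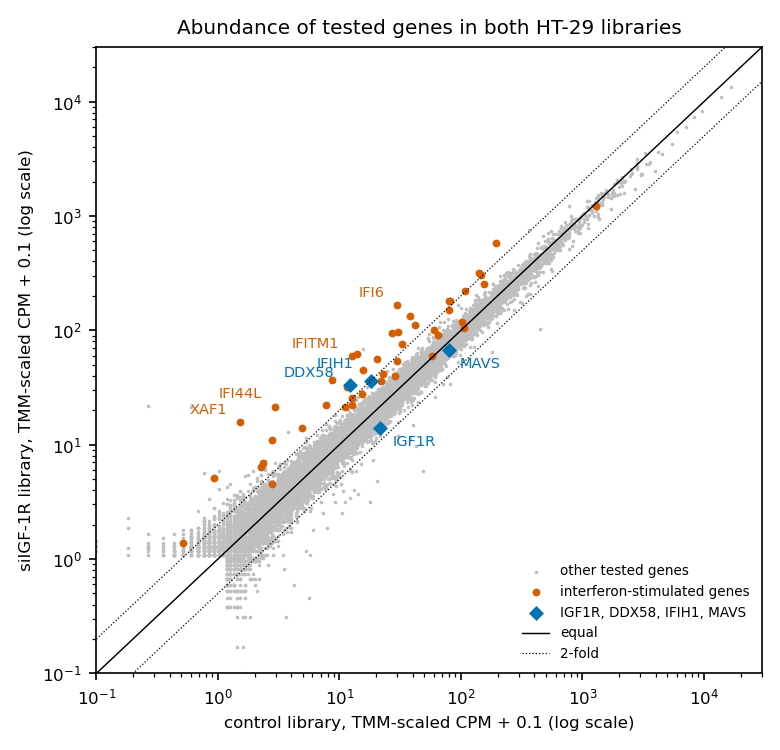
TMM-scaled abundance of each tested gene in the control library (x axis, CPM plus 0.1, log scale) and the siIGF-1R library (y axis, same unit), with interferon-stimulated genes in orange, IGF1R, DDX58, IFIH1 and MAVS as blue diamonds, the line of equality and dotted lines at 2-fold. Of 44 interferon-stimulated genes, 28 lie beyond the upper 2-fold line by the rule used, and IGF1R lies below equality.

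Interferon-stimulated genes were higher in the siIGF-1R library almost throughout the list. Of 44 tested members, 41 had intervals above 1, 2 spanned 1 and 1 lay below it, and 28 were at least 2-fold higher. The median log2 ratio was 1.20, above all 10000 random lists, whose central 95% ran from -0.09 to 0.07. XAF1, which encodes an antagonist of the apoptosis inhibitor XIAP, was 10.8-fold higher (interval 6.76 to 19.4), with 221 reads against 17. IFI44L was 7.46-fold higher (5.28 to 11.1) and IFI6 5.55-fold (4.96 to 6.23). TRIM22, with 70 reads against 10, was 5.75-fold higher. IFITM1, which restricts viral entry, was 4.76-fold higher and the antiviral GTPases MX2 and MX1 4.22-fold and 3.51-fold. OAS2, which makes the activator of RNase L, was 4.50-fold higher.

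Both RNA sensors of the series title were higher in the siIGF-1R library. DDX58 was 2.74-fold higher (log2 ratio 1.46, interval 1.19 to 1.74), with 468 reads against 145. IFIH1 was 1.99-fold higher (log2 ratio 0.99, interval 0.76 to 1.23), with 508 reads against 217. The related helicase DHX58 was 1.72-fold and the transcription factor IRF7 1.71-fold higher. The ratios of these genes and of both sensors lay within the range of the interferon-stimulated list. Whether they differed apart from that list was not tested. MAVS, the mitochondrial adaptor through which both sensors signal, was 1.18-fold lower (log2 ratio -0.23, interval -0.36 to -0.10). This difference was close in size to the standard deviation of 0.227 among the genes with the most reads. Of 17 tested genes of cytosolic RNA sensing, 7 had intervals above 1, 2 below and 8 spanning it. Their median of 0.12 lay at percentile 96.4 and did not stand apart, but it did with matching on length and after removal of the GC trend (0.13), as did the mean over members (0.26), whereas it lay at percentile 78.5 with 1 added to the RPKM values.

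Genes of MHC class I antigen presentation and of endosomal and DNA sensing were higher by less. Whether these lists differed apart from the interferon-stimulated list was not tested, so they are not separate findings. Of 20 genes of MHC class I antigen presentation, 15 had intervals above 1, 2 below and 3 spanning it, with a median log2 ratio of 0.31 above all random lists. NLRC5, the transactivator of these genes, had a log2 ratio of 0.99, HLA-F of 0.80, the peptide transporter gene TAP1 of 0.68 and B2M of 0.66. The 11 genes of endosomal and DNA sensing had a median of 0.39 (percentile 99.97), with 5 intervals above 1, 2 below and 4 spanning it. Among members with at least 50 reads, the nucleic acid sensor ZBP1 was at 2.07 (46 reads against 9) and the endosomal RNA receptor TLR3 at 0.53. The 10 tested interferons, receptors and JAK kinases did not stand apart (median -0.06, percentile 25.7), with 1 interval above 1, 2 below and 7 spanning it, IFNAR1 at -0.30, IFNGR2 at 0.24 and the type I interferon gene IFNE at -0.39 (33 reads against 37) with an interval spanning 1. The 18 NF-kB target genes did not stand apart either (median 0.16, percentile 95.3, mean 0.03), with 1 interval above 1, 4 below and 13 spanning it, TRAF1 at 0.54 and both NFKB2 and NFKB1 at -0.38. HT-29 is an epithelial line, and of the immune cell markers 4 reached the filter, with CD14 at 0.09, CD68 at -0.14 and LYZ, which HT-29 cells expressed at 11427 and 8037 reads, at 0.28. Of the markers of fibroblasts and endothelium 2 reached it, among them ACTA2 at 1.54 (42 reads against 12).

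**Figure D2:**
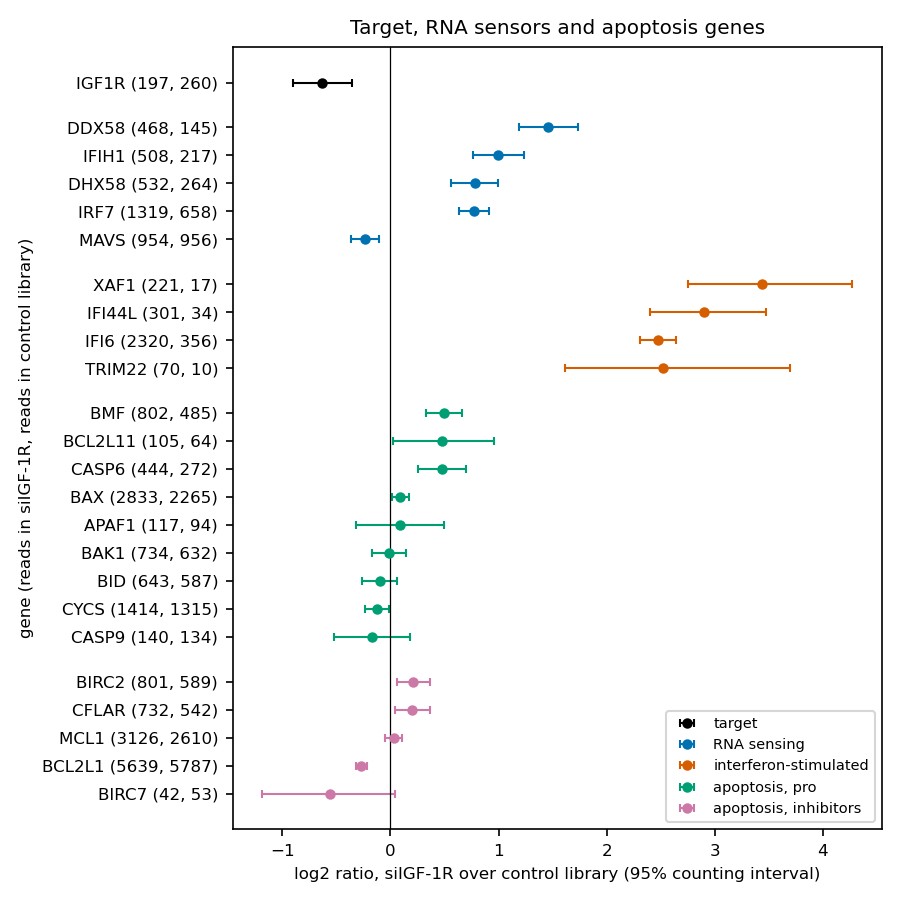
Log2 ratios of siIGF-1R over control library (x axis) for IGF1R, RNA-sensing genes, leading interferon-stimulated genes and apoptosis genes, with reads in each library in parentheses and bars for the 95% counting interval. DDX58 (1.46) and IFIH1 (0.99) lie well to the right of 0, whereas BAX (0.09), BAK1 (-0.02) and CASP9 (-0.17) lie near it.

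Genes of mitochondrial apoptosis differed little between the libraries. Of 21 tested pro-apoptotic genes, 7 had intervals above 1, 2 below and 12 spanning it, and their median log2 ratio of 0.01 lay at percentile 61.5. The BH3-only genes BMF (0.49) and BCL2L11 (0.48, interval 0.02 to 0.95) were higher, as was CASP6 (0.48). BAX, an effector of outer membrane permeabilization, had a log2 ratio of 0.09 (interval 0.01 to 0.17). BAK1 (-0.02), BID (-0.10), APAF1 (0.08) and CASP9 (-0.17) had intervals that spanned 1, and CYCS (-0.13, interval -0.24 to -0.02) was lower. Among 11 apoptosis inhibitors, 3 were above 1, 2 below and 6 spanned it (median 0.13, percentile 96.3). BCL2L1, the gene of BCL-XL, was 1.20-fold lower (log2 ratio -0.27, interval -0.32 to -0.22), MCL1 was at 0.03, BIRC2 at 0.21, CFLAR at 0.20 and BIRC7 at -0.56 with an interval spanning 1. Set against the standard deviation of 0.227 among the genes with the most reads, CYCS lay within it and BCL2L1 little beyond it. BCL2 had 0 reads in the siIGF-1R library and 2 in the control, too few for a ratio. The 12 genes of the death receptor pathway had a median of 0.02 (percentile 62.4), with CASP10 at 0.49, the ligand gene TNFSF10 (TRAIL) at 0.38, its receptor gene TNFRSF10B at -0.32 and TNFRSF1A at -0.43.

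Target genes of the ERK pathway and genes of ribosome biogenesis were lower, and G2/M genes were higher. Genes of PI3K-AKT-mTOR signalling did not stand apart. That list holds components of the pathway and not its target genes, so it cannot be compared with the ERK list as a measure of pathway output. The 14 feedback and target genes of the ERK pathway had a median log2 ratio of -0.27 (percentile 0.02), with 8 intervals below 1 and 6 spanning it. FOSL1 was at -0.82, MYC at -0.56, ETV5 at -0.41 and DUSP5 at -0.42 with an interval spanning 1. The 21 genes of PI3K-AKT-mTOR signalling had a median of -0.04 (percentile 34.0), with 3 intervals above 1, 7 below and 11 spanning it, RICTOR at 0.52, RPTOR at -0.41 and EIF4EBP1 at -0.37. The list of 14 immediate early genes had a median of -0.12 (percentile 6.34), with FOSB at -0.58 and JUN at -0.27, and stood apart only by the mean of its members (-0.21). Ribosome biogenesis genes were lower, with 13 of 25 intervals below 1 and 1 above (median -0.12, percentile 1.68), among them BOP1 (-0.86), RRP12 (-0.71) and RRP9 (-0.70). S-phase genes had 9 of 25 intervals below 1 and 1 above (median -0.14, percentile 1.32), including CDC45 (-0.36) and MCM2 (-0.32), but did not stand apart by their mean (-0.11) or after removal of a length trend (-0.12). G2/M genes had 17 of 26 above 1 and 4 below (median 0.17, percentile 99.99), including TOP2A (0.32) and CDC25C (0.30), and their median was 0.10 after removal of the GC trend and matching on GC content (percentile 99.92). The 19 p53 target genes had a median of -0.17 (percentile 0.48), with 5 intervals below 1, 2 above and 12 spanning it. GDF15, a stress-induced cytokine, was 2.41-fold lower (479 reads against 982), whereas TP53INP1 was 3.09-fold higher (81 against 22). This list did not stand apart after removal of the GC trend (-0.11, percentile 4.05) or by the mean of its members (-0.11).

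Genes of the ER stress and amino acid response were lower, with 17 of 26 intervals below 1, 2 above and 7 spanning it (median -0.27, below all random lists). The members with the largest ratios were ATF3 (-1.19, 43 reads against 84), TRIB3 (-0.87), the serine synthesis gene PSAT1 (-0.87) and the amino acid transporter gene SLC7A5 (-0.83). The list of metallothionein genes, which encode metal-binding proteins, was drawn up to include the transporter gene SLC30A1 as well. It had a median of -0.83 over 7 tested genes, 5 with intervals below 1 and 2 spanning it. MT1G was 4.23-fold lower (interval 2.91 to 6.45), MT1F 3.35-fold, MT2A 1.79-fold and MT1E 1.76-fold. The metallothionein genes resemble each other, and the assignment of reads between them is uncertain. Glycolysis genes had 13 of 19 intervals below 1 and 1 above (median -0.21, percentile 0.23), with HK2 at -0.62, GPI at -0.59 and the glucose transporter gene SLC2A1 at -0.47, and their median was -0.13 after removal of the GC trend and matching (percentile 1.75). Of 13 mitochondrially encoded mRNAs, 12 had intervals below 1 (median -0.33, below all random lists), including ATP6 (-0.39) and ND4 (-0.36). The 33 nuclear genes of oxidative phosphorylation had a median of 0.11 (percentile 99.99), with 16 intervals above 1 and 8 below, COX6C at 0.48 and CYC1 at -0.38, and their median was 0.07 after removal of the GC trend and matching (percentile 99.02) and 0.04 after removal of a length trend. The 59 ribosomal protein genes had a median of 0.03 (percentile 99.9) with 26 intervals above 1 and 19 below, RPL37 at 0.42 and RPS2 at -0.45. This value changed sign after removal of a trend on gene length (-0.02), and the list did not stand apart when matched on length. The 8 tested non-polyadenylated and nuclear RNAs had a median of -0.38 (percentile 0.14), which included RN7SL1 and RN7SL2, and the list did not stand apart with a 5 CPM filter or with no filter (-0.21 with each).

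**Figure D3:**
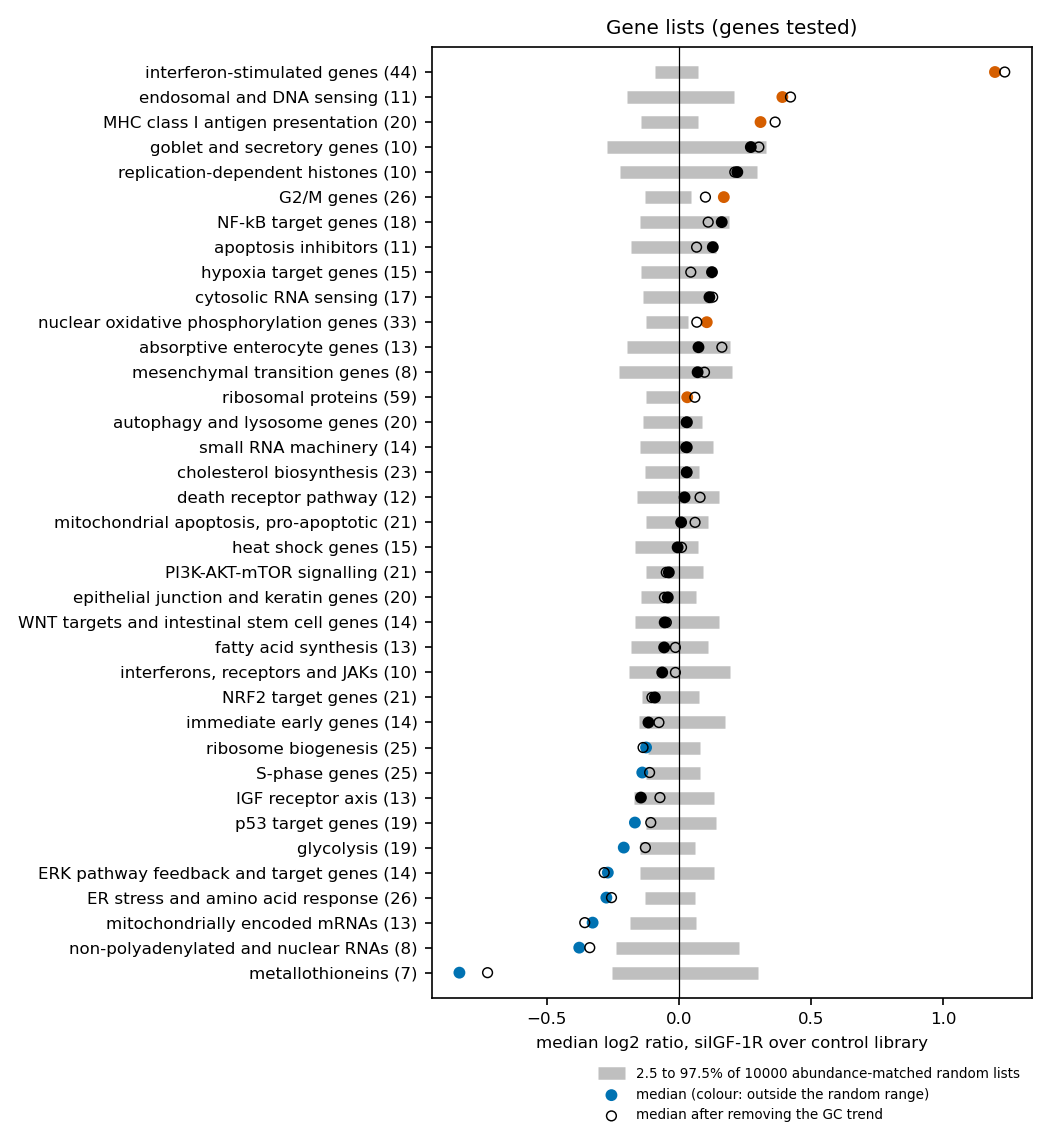
Median log2 ratio (x axis) of each gene list, with the number of genes tested in parentheses, against the central 95% of 10000 abundance-matched random lists (grey bars). Filled points are medians, orange above and blue below the random range, and open points are medians after removing the GC trend. Interferon-stimulated genes (1.20) lie farthest to the right and metallothioneins (-0.83) farthest to the left.

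The remaining lists did not stand apart. Among NRF2 target genes (median -0.09, percentile 16.2), AKR1C2 was at 0.88 and the ferritin gene FTL at -0.68. Hypoxia target genes had a median of 0.13 (percentile 97.2), with KDM3A at 0.38. Cholesterol biosynthesis genes had a median of 0.03 (percentile 85.0), with INSIG1 at 0.41 and SREBF2 at -0.44, and fatty acid synthesis genes one of -0.06 (percentile 38.2), with ACLY at -0.21. Goblet and secretory genes had a median of 0.27 (percentile 94.9) with AGR3 at 0.89 and AGR2 at 0.51, and stood apart only after GC removal and matching (0.30, percentile 97.8). Absorptive enterocyte genes were at 0.07 (percentile 78.8), with PHGR1 at 1.15 and KRT20 at 0.44. The 14 WNT target and intestinal stem cell genes had a median of -0.05 (percentile 28.99), with SOX9 at -0.66 and ASCL2 at 0.79. Epithelial junction and keratin genes (-0.04, percentile 46.8), mesenchymal transition genes (0.07, percentile 79.1), autophagy and lysosome genes (0.03, percentile 82.4), heat shock genes (-0.0046, percentile 75.2), small RNA machinery (0.03, percentile 69.2) and a list of mainly replication-dependent histones (0.22, percentile 92.1) also lay within the random range. In the small RNA machinery, ADAR, an editor of double-stranded RNA, was at 0.37.

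The ratios followed transcript GC content. Across 11056 genes with at least 100 reads, Spearman's rho between GC content and the log2 ratio was -0.33, a relation across genes of 2 libraries in which genes are not independent replicates. With the genes split into 10 bins of equal number, the median log2 ratio went from 0.14 in the bin of lowest GC content to -0.11 in the bin of highest. Gene model length had a rho of -0.02 over 12127 genes.

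**Figure D4:**
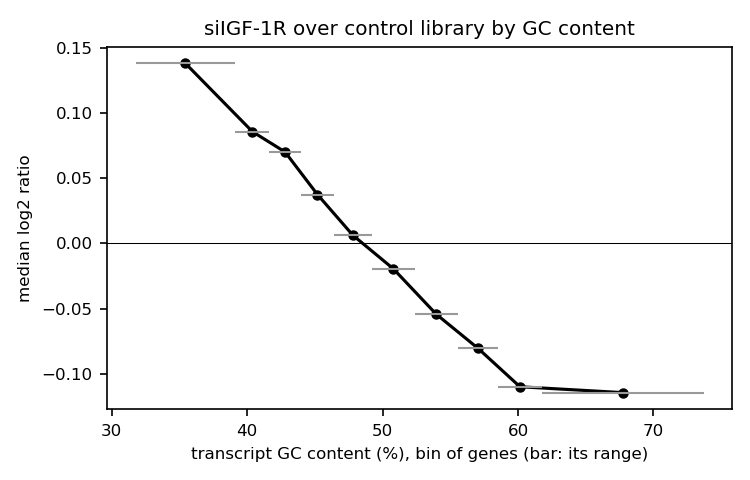
Median log2 ratio of siIGF-1R over control library (y axis) in 10 bins of genes by transcript GC content (x axis, percent, with grey bars for the range of each bin). The medians go from 0.14 at the lowest to -0.11 at the highest GC content.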

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

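The tests that removed the GC trend, matched on GC content, used an mRNA background or counted mRNA rows were chosen after the results were seen. The IGF1R log2 ratio stayed below 0 under all 9 alternatives (-0.64 to -0.34). Its value lay outside the counting interval only with 1 added to the RPKM values (-0.34), where the added value shrinks ratios of low genes. The counts of genes at least 2-fold higher and lower were 72 and 32 with 1 added to the RPKM values, 59 and 37 with a 5 CPM filter, 519 and 384 at 1.5-fold, 39 and 27 at 4-fold, 42 and 33 with the whole interval beyond 2-fold, and 130 and 74 among mRNA rows. The count of lower genes was 221 with no low-count filter and 94 with an added count of 5. The filters and folds change these counts by construction, and most calls thus rest on genes of low count. Higher genes were 61.9% of calls in the main setting and between 61.7% and 69.5% under the other scalings of counts, and 70.8% with 0.1 added to the RPKM values. The interferon-stimulated genes stood apart in every setting tried (median or mean 1.10 to 1.30). The IGF receptor axis stood apart with a length trend removed (-0.1882) and by its mean (-0.188, IGF1R included), but lay farther inside the random range with the GC trend removed and GC matching (-0.07, percentile 14.7). Cytosolic RNA sensing stood apart with the GC trend removed (0.1281), also with GC matching (0.1281), with length matching (0.1159) and by its mean (0.2586), but not under the other alternatives, and it lay farther inside the random range with 1 added to the RPKM values (percentile 78.53) and with a 5 CPM filter. For neither list was the cause tested. The seed difference was 0.0519 for the hexamer, -0.0472 for the passenger strand's heptamer, 0.0585 with a 5 CPM filter and -0.0038 with the GC trend removed, none outside the limits. Ribosomal proteins changed sign with a length trend removed (-0.0152, the cause was not tested). Of the values of named genes under alternatives, 1473 stayed within the counting interval and 115 moved out of it, but none reversed a ratio whose interval excluded 1. No paired analysis was possible because each group holds 1 library, and for the same reason no replicate could be left out. Depth limits the low genes most.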

Other observations

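The tests of shared 7SL reads, of the GC trend in the non-polyadenylated and nuclear RNAs and of the sets of early and sustained genes were chosen after the result was seen, and so was the removal of the GC trend as a setting. A set of 15 genes taken as sustained late in an interferon response had a median log2 ratio of 1.57 (quartiles 1.11 and 2.21). A set of 9 tested genes taken as induced early by IRF3 or NF-kB had a median of 0.19 (quartiles -0.02 and 0.79). All 15 genes of the sustained set belong to the interferon-stimulated list. The 2 members of that list with intervals spanning 1, IRF1 and ISG20, were placed in the early set. The contrast thus follows in part from the choice of members and does not decide the stage of a response. Both sets were written after the libraries were seen, and the early set's members went both ways, with ATF3 at -1.19. Of 6 interferon genes looked at in the same way, 4 had no read in either library, and IFNL3 and IFNG had 1 read each in the siIGF-1R library. These counts lie under the limit that a count of 0 allows, so a difference in these 6 genes was not detectable at this depth, whereas IFNE had 33 reads in the siIGF-1R library and 37 in the control. SMN1 and SMN2, near-identical copies chosen after their values were seen, together had 115 reads against 251, 2.55-fold lower (interval 2.05 to 3.22).

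The higher interferon-stimulated genes were set against 3 explanations. The GC trend is argued against as the cause, because the list's median was 1.234 after the trend was removed, against 1.20 before. Admixed leukocytes are argued against by 9 lymphoid and pan-leukocyte markers, which summed to 5 reads in the siIGF-1R library and 5 in the control library, with at most 4 reads for any marker (CD79A). Sensing of the transfected RNA itself, rather than loss of IGF1R, cannot be told apart from the knockdown, since 0 libraries are labelled as given a non-targeting siRNA. With 1 library per group, a difference between cultures also stays open, so the hypothesis that IGF1R loss raises these genes is untested here.

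The lists lower in the siIGF-1R library may in part follow the GC trend, and each was placed again after the trend was removed and random lists were matched on GC content. The percentile stayed below 2.5, with over 50% of the median kept, for ERK pathway genes (0), the ER stress and amino acid response (0), mitochondrially encoded mRNAs (0), metallothioneins (0.005), ribosome biogenesis (0.29), the non-polyadenylated and nuclear RNAs (0.275, median -0.34 against -0.38 before), glycolysis (1.75, median -0.13 against -0.21 before) and S-phase genes (1.83). For these lists the trend is argued against as the whole cause, although S-phase genes did not stand apart by their mean (-0.1052) or with a length trend removed (-0.1175), and the non-polyadenylated and nuclear RNAs did not stand apart with a 5 CPM filter (-0.2086). The p53 target genes moved from a median of -0.17 (percentile 0.48) to -0.11 (percentile 4.475), so the trend remains a candidate explanation for that list, whose median shrank toward 0. A difference between the cultures or library preparations stays open for all of them.

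The 4 rows of 7SL RNA with the most reads, picked because they were low, were lower by log2 ratios between -3.82 and -2.13. Summed over all 6 rows of 7SL RNA in the table the reads were 6.07-fold lower (237 against 1228), so a shift of reads among these rows alone does not account for the ratios. Reads lost to further near-identical copies cannot be told apart from a lower level, since GENCODE 29 names 680 such genes and the table holds 6 of them. A lower yield of all short non-polyadenylated RNAs is argued against as the whole cause. The 28 other rows of such types with at least 50 reads had a median of -0.1768 with quartiles of -0.40 and 0.34. Of these, 24 were snoRNAs and 2 were of rRNA type, without a limit on length. Some leaned lower by less than 7SL. The summed snoRNA reads were at -0.41, and RN7SK was at -0.43 and RMRP at -0.32, each with an interval spanning 1. A small loss of yield thus stays open. A difference in 7SL itself or in how its fragments were captured in 1 of the libraries may remain, and no value here decides between them.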
